A study of Mus musculus with 2 samples.

How the data were processed

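CD45+ cells of subcutaneous Colon26 tumours were measured in 14 mice, each marked by 1 hashtag antibody. Per the labels' protocols, the tumours were digested for 60 min with Liberase and DNase, tumour and dead cells were removed on 40% Percoll, and cDNA was made on the BD Rhapsody whole-transcriptome system. The labels place all mice in 1 hashtagged cDNA library and also speak of separate experimental runs. No run is given for any mouse, so batch and group could not be told apart where runs differed.

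Per the labels, the authors trimmed reads with cutadapt 2.10, aligned them to mm10 with Bowtie2 2.3.4.1 and handled them with Seurat 2.3.4. They kept barcodes above the inflection of the knee plot and assigned mice and doublets by the fold change of hashtag reads. The deposited table holds whole-number read counts of 22836 genes in 8262 barcodes. A median of 10 reads per nonzero entry, a mean of 26.8 and a share of 18.0% of entries equal to 1 are those of reads not collapsed by molecular identifier. Reads of 1 molecule are not independent, and all tests therefore took the mouse as the unit. The log(TPM+1) values of the authors' own analyses were not used here.

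Barcodes that the deposited table names as doublets (141) or without a detected hashtag (6) were left out of every step, 147 in all. Of 8115 barcodes of the 14 mice, 383 with more than 25% of counts in the 36 mitochondrial genes were removed. None had fewer than 200 genes (lowest 201), and 7732 were kept, against 7613 that the labels state under another filter. Gene symbols were those of the table, of which 18488 are in GENCODE M21.

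Total kept counts per mouse ran from 26007834 to 51230461 and the median count per cell from 30312 (minP1_PDL1_3) to 57305 (PDL1_1). Counts were scaled to a common total per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 nearest neighbours went into Leiden clustering at resolution 1.0, with seed 0. A cluster took the name of a cell type when at least 3 of that type's markers were among its top 50 genes by fold, taken over genes found in at least 25% of its cells. That number of markers was set after the clusters had been seen, and clusters below it stayed unnamed and kept their own share. A doublet score was the share of simulated doublets among 50 neighbours. Of the kept cells 24.5% lay over 0.5, and 74.4% of simulated doublets did.

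Shares of 24 cell classes per mouse were compared over the 4 groups by a permutation test of F with 100000 permutations, with Benjamini-Hochberg adjustment over the classes. Pairs of groups were compared by two-sided exact permutation of the mouse labels. The ratio of CD8 to regulatory T cells was taken as log2 with 0.5 added to each count.

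Counts were summed per mouse over all CD45+ cells and over T cells, NK cells, monocytes and macrophages, dendritic cells and neutrophils, where a mouse had at least 10 cells of the class. Control_1 had fewer than 10 neutrophils, which left 13 mice and 2 Control mice for that class. The sums were tested with edgeR quasi-likelihood fits (TMM normalization, filterByExpr, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 passed. The genes tested numbered 18410 in all CD45+ cells, 12505 in T cells, 11501 in NK cells, 15175 in monocytes and macrophages, 11988 in dendritic cells and 9610 in neutrophils. Values are log2 changes with their standard error (SE), and CPM (counts of the gene scaled to a common library total) as the mean and SD of mice.

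Gene lists (22) and marker lists of cell types (22) fixed before the data were examined were tested with camera of limma, two-sided, at a preset correlation between genes of 0.01 and a prior count of 3, with all their p adjusted over the lists of a kind. Lists of fewer than 3 tested genes were left out. Each list was also tested with a correlation estimated from the data, and its members were adjusted over the list alone. A list rose or fell as a whole, and the number of members above or below is a count of signs.

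The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. So was the rule for naming genes. Of genes past the threshold, up to 8 in each direction and up to 10 members of the lists, by adjusted p, could be named. With fewer than 3 genes past the threshold none was called and the 3 of smallest p were given as values. A set of 15 genes of the treated axis was always computed. Members of lists given as examples beside a list, and not past the threshold themselves, fall outside this rule and were chosen after their values were seen.

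The alternatives chosen beforehand were DESeq2, RLE normalization, no filter on low counts, no cell filter, clustering resolution 0.5, at least 20 cells per mouse and class, edgeR on cells per class, the replicate number as a block, an estimated correlation, and each mouse left out in turn. Alternatives added after the data had been seen left out the 2 clusters of non-immune cells, a macrophage cluster of mixed lineage or cells of doublet score over 0.5, kept only genes in at least 10% of cells, or counted cells with at least 2 reads of a gene in place of reads.

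The tests were tested on simulated data drawn from the fitted means and dispersions of these mice, in 3 simulations with 200 changed genes each, for minP1_PDL1 against Control. Changes of 2-fold and 4-fold were recovered for 34.0% and 61.0% of genes in all CD45+ cells, 16.3% and 37.0% in T cells, 8.0% and 33.3% in NK cells, 33.3% and 60.7% in monocytes and macrophages, 5.33% and 30.7% in dendritic cells, and 0% and 4.33% in neutrophils. A share moved by 6 points was called in 16 of 40 simulations, and 4 of 920 unchanged shares were called. Absence of a passing gene therefore bounds no change of 2-fold at this depth.

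Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, leidenalg 0.10.2 and python-igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.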

Results

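The data were single-cell transcriptomes of CD45+ cells (leukocytes) from subcutaneous tumours of Colon26, a mouse colon carcinoma line, in 14 BALB/c mice. Untreated Control mice (n = 3) were set beside mice given minP1 (n = 4), anti-PD-L1 antibody (PDL1, n = 3) or both (minP1_PDL1, n = 4). The peptide minP1 is derived from HMGN1, a nucleosome-binding protein that acts as an immunostimulatory signal outside the cell. PD-L1 is the ligand, encoded by Cd274, of the inhibitory T cell receptor PD-1. The peptide was injected on day 9 (0.08 µg) and the antibody on days 4 and 8 (200 µg each), and tumours were taken on day 10. After the cell filter 7732 cells remained, from 466 cells in PDL1_2 to 724 in minP1_3, where the number after the group name is the replicate. Total counts per mouse ran from 26007834 (PDL1_2) to 51230461 (Control_2), and the median cell held 36390 counts over 1979 genes.

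Monocytes and macrophages, T cells and NK cells held most kept cells, at similar shares in the 4 groups. Monocytes and macrophages took 32.7% ± 6.85 (SD) of cells in Control, 36.4% ± 6.99 in minP1, 32.3% ± 1.07 in PDL1 and 33.7% ± 4.87 in minP1_PDL1. T cells took 25.5% ± 3.31, 25.5% ± 5.74, 22.9% ± 3.31 and 23.2% ± 3.36, and NK cells 17.0% ± 2.58, 15.9% ± 1.80, 14.6% ± 3.49 and 16.1% ± 2.91. Each of these 3 classes had an adjusted p of 0.906 in a permutation test over the 4 groups. Dendritic cells took 5.80% ± 0.335, 6.05% ± 0.643, 6.88% ± 0.234 and 6.19% ± 0.609 (adjusted permutation p = 0.543). Regulatory T cells, the Foxp3-bearing suppressive subset, took 7.93%, 7.29%, 6.47% and 7.498%, and the CD8 T cell cluster took 4.82%, 4.04%, 4.95% and 4.53%. The log2 ratio of CD8 to regulatory T cells was -0.71 ± 0.32 in Control, -0.86 ± 0.80 in minP1, -0.32 ± 0.65 in PDL1 and -0.80 ± 0.50 in minP1_PDL1. With T cells called by counts 3 of its comparisons reversed in sign. None of its 5 comparisons passed, with two-sided exact permutation p from 0.286 (minP1_PDL1 against PDL1) to 0.886 (minP1_PDL1 against minP1).

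**Figure D1:**
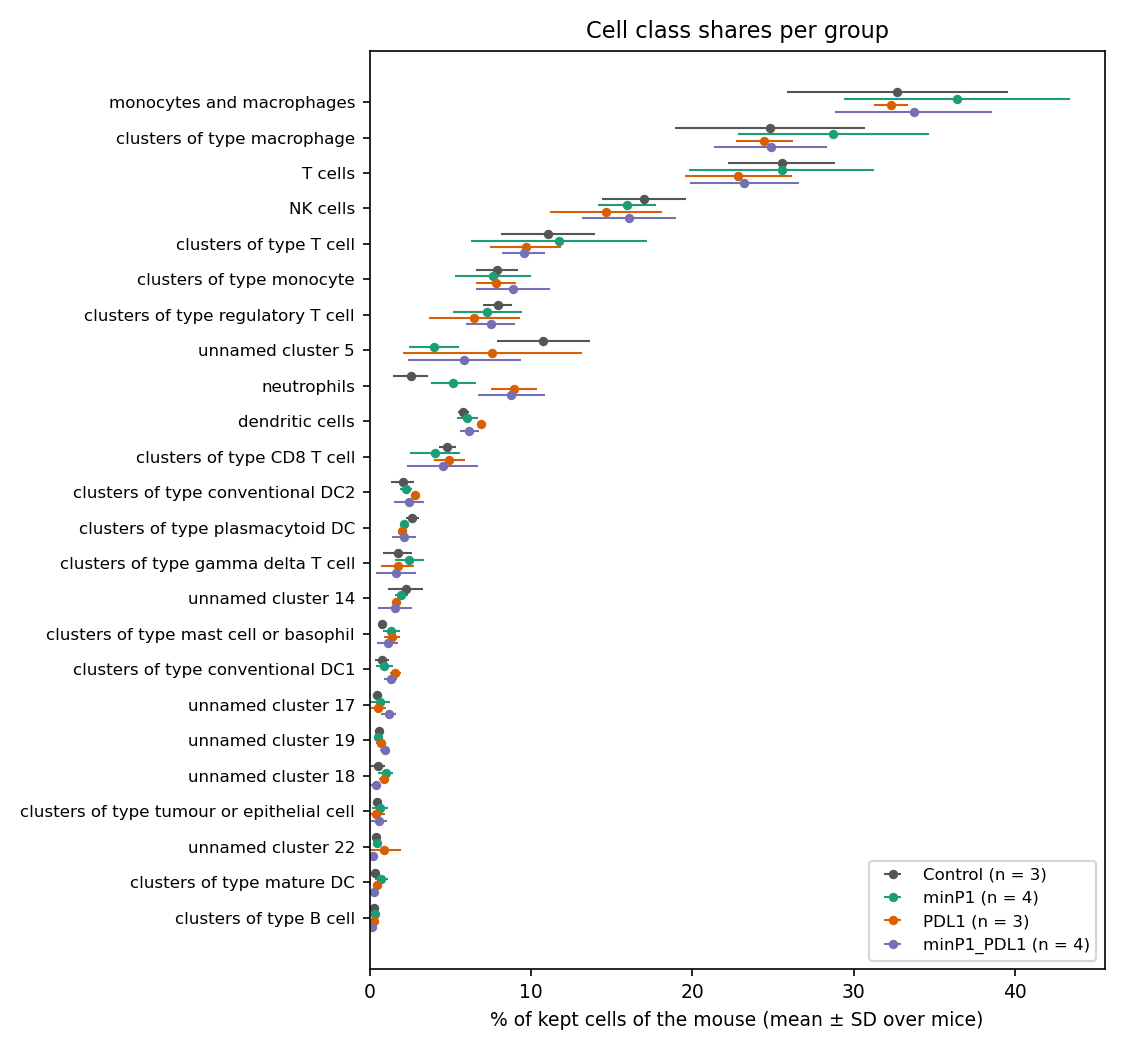
Share of each cell class in the kept cells of a mouse (x axis, %), as the mean of each group with its SD as a bar. Neutrophils ran from 2.55% in Control to 8.96% in PDL1, and monocytes and macrophages from 32.3% to 36.4%.

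Neutrophils, short-lived phagocytes marked here by S100a8, S100a9 and Cxcr2, changed in share among the groups. They took 2.55% ± 1.08 of cells in Control (n = 3 mice), 5.20% ± 1.40 in minP1 (n = 4), 8.96% ± 1.43 in PDL1 (n = 3) and 8.79% ± 2.06 in minP1_PDL1 (n = 4). They were the 1 class of 24 that passed the permutation test over the 4 groups (F = 12.3, p = 0.00125, adjusted p = 0.030). The mean share was 3.51 times Control with anti-PD-L1 alone (two-sided exact permutation p = 0.1, the smallest that 3 against 3 mice allow) and 3.44 times Control with both agents (exact p = 0.0286, the smallest that 3 against 4 allow, adjusted p = 0.457). With minP1 alone it was 2.04 times Control (exact permutation p = 0.0857). The minP1_PDL1 mean exceeded that of minP1 1.69 times (exact permutation p = 0.0571) and lay 0.174 points under that of PDL1, which did not pass by the same test. No pairwise exact test passed after adjustment over 24 classes, while edgeR on cells per class passed for PDL1 (log2 1.81, adjusted p = 0.000979) and minP1_PDL1 (1.79, 0.000649) against Control. The omnibus call ended without Control_1 (adjusted permutation p = 0.123), Control_2 (0.115), minP1_2 (0.0691), minP1_4 (0.0782), PDL1_3 (0.0670), minP1_PDL1_3 (0.0814) or minP1_PDL1_4 (0.0806), and after cells of high doublet score were left out (0.0984).

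**Figure D2:**
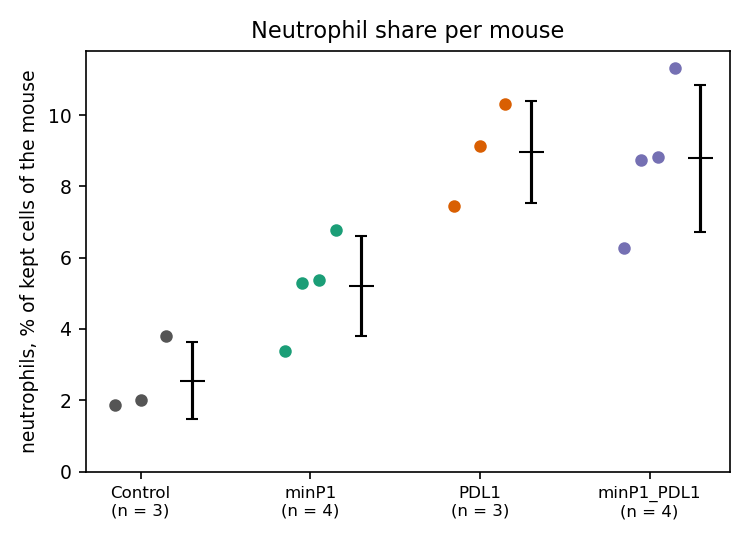
Neutrophils as a share of the kept cells of each mouse (y axis, %), with 1 dot per mouse and the group mean and SD as the bar beside the dots. Control mice lay between 1.86% and 3.79%, PDL1 mice between 7.45% and 10.3%, and minP1_PDL1 mice between 6.26% and 11.3%.

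Shares of other classes did not pass. An unnamed cluster of Mgp, Sparc and Col1a2 transcripts, genes of stromal matrix, took 10.8% ± 2.88 in Control, 4.01% ± 1.54 in minP1, 7.60% ± 5.54 in PDL1 and 5.87% ± 3.51 in minP1_PDL1 (adjusted permutation p = 0.543). The minP1 share of this cluster was 0.372 times that of Control (two-sided exact permutation p = 0.0286, adjusted p = 0.343). Plasmacytoid dendritic cells, a type I interferon producing subset, took 2.66% in Control and 2.11% in minP1 (exact permutation p = 0.0286, adjusted p = 0.343). Conventional DC1, the cross-presenting subset, took 0.767%, 0.922%, 1.59% and 1.32%, and mature DC (37 cells, 70.3% of them over a doublet score of 0.5) took 0.322%, 0.735%, 0.480% and 0.280%. Cells per mouse were 544 ± 89.6, 632 ± 69.3, 484 ± 19.0 and 530 ± 31.3, and minP1_PDL1 against minP1 had a two-sided exact permutation p of 0.0286. That was the 1 of 15 comparisons of cells, depth and mitochondrial share with an unadjusted exact p under 0.05, and it was the smallest p the design allows.

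Mice given minP1 alone were compared with Control mice. In all CD45+ cells the MHC class II and complement lists rose and the cell cycle list fell, each p = 0.976 with an estimated correlation. Each of the 13 measured genes of MHC class II presentation, which displays antigen to CD4 T cells, lay above Control, with a median log2 change of 0.33 (n = 4 against 3 mice, adjusted p = 0.00776). Cd74, the class II chaperone, had 2492 ± 346 CPM (SD) against 1967 ± 372 in Control. Among complement and phagocytosis genes 16 of 18 lay above Control (median 0.39, adjusted p = 0.00347). Cell cycle genes lay below Control in 28 of 30 (median -0.21, adjusted p = 0.000203). Of these members 0 passed, either over all genes or adjusted over the list alone. Macrophage markers moved with them (median 0.50, 11 of 12 above, adjusted p = 0.00741), as did conventional DC2 markers (0.34, 0.0297), conventional DC1 markers (0.41, 0.0462), neutrophil markers (0.39, 0.0462), B cell markers (0.94, 0.0364) and eosinophil markers (0.76, 0.00316), and fibroblast markers fell (-1.33, 6 of 6 below, 0.000154). With an estimated correlation these had adjusted p = 0.561, 0.534, 0.561, 0.863, 0.561, 0.140 and 0.140. Without the 2 clusters of non-immune cells MHC class II had an adjusted p = 0.245, and of these markers only those of macrophages and eosinophils passed. Without Control_1, 1 list passed and MHC class II and complement had adjusted p = 0.350 and 0.342. Without minP1_4 MHC class II had 0.0897, and without minP1_1 6 lists passed.

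In monocytes and macrophages of minP1 mice, type I interferon response genes, the antiviral programme, fell. Of 26 members 25 lay below Control, with a median log2 change of -0.36 (adjusted p = 1.4e-10, and p = 0.522 with an estimated correlation), and 1 member passed adjusted over the list alone. The level of this list was 3.13, 2.44 and 2.84 in Control and 1.94, 2.57, 2.49 and 2.48 in minP1 (adjusted p = 0.000173 without Control_1). Isg20, an interferon-induced exonuclease, had 22.7 ± 3.89 CPM against 49.0 ± 10.5 in Control (log2 -1.11, SE 0.19, adjusted p = 0.655). Genes of the regulatory T cell programme also fell, with 15 of 16 below (median -0.32, adjusted p = 5.5e-05, and p = 0.522 with an estimated correlation). Regulatory T cell markers, a list that shares members with it, moved alike (median -0.43, 7 of 7 below, adjusted p = 0.00076, and p = 0.698 with an estimated correlation). Smaller shifts passed for hypoxia and glycolysis (0.13, adjusted p = 0.00402), DC maturation (-0.20, 0.00577), NF-kB and TLR response (-0.15, 0.00577), cell cycle (-0.15, 0.00843) and MHC class I (-0.09, 0.00948). Each of these 5 had an adjusted p = 0.734 with an estimated correlation. Hypoxia lost its call without minP1_2 (0.0681), DC maturation without Control_3 (0.0694), and NF-kB without Control_1 (0.135) or minP1_4 (0.0765). Cell cycle lost it without Control_2 (0.396) or minP1_3 (0.191), and MHC class I without Control_1 (0.0992), Control_3 (0.0948) or minP1_1 (0.0616). Without the cluster of mixed lineage or cells of high doublet score (over 0.5) the regulatory T cell programme (0.232 and 0.516), its markers (0.476 and 0.663) and hypoxia (0.659 and 0.506) were lost, as were cell cycle without that cluster (0.457) and DC maturation (0.162), NF-kB (0.297) and MHC class I (0.129) without those scores.

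In NK cells of minP1 mice, DC maturation genes fell (median -0.50, 14 of 16 below, adjusted p = 0.0208, and p = 0.267 with an estimated correlation), as did interferon gamma response genes (-0.29, 17 of 22 below, 0.0208, and p = 0.524 with an estimated correlation). Both NK calls ended without Control_3 (adjusted p = 0.259), minP1_4 (0.113) or minP1_1 (0.104 and 0.0525), interferon gamma also without Control_2 (0.0707), and DC maturation without high doublet scores (0.146). Cell cycle genes rose in dendritic cells (median 0.43, 22 of 30 above, adjusted p = 0.0257, and p = 0.990 with an estimated correlation). That call ended without Control_2 (0.0747), Control_3 (0.443), minP1_1 (0.135) or minP1_3 (0.0732). No list passed in T cells or neutrophils by camera, although T cells had 1 without Control_2, 2 without minP1_2 and 3 without minP1_4, and neutrophils 2 without minP1_1 or minP1_2.

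No single gene passed between minP1 and Control. In all CD45+ cells edgeR called 0 of 18410 genes, 1278 had an unadjusted p under 0.05 where 920 are expected by chance, and DESeq2 called 38. The 1278 became 732 without Control_1 (958 expected) and 768 without the 2 clusters of non-immune cells (867 expected). The 3 genes of smallest p were Ogn, a matrix proteoglycan, at 21.9 ± 4.35 CPM against 102 ± 32.2, Csf1, the macrophage growth factor, at 75.3 ± 5.07 against 127 ± 24.6, and Coro1c at 46.3 ± 2.07 against 34.1 ± 3.08 (each adjusted p = 0.564). Without the 2 clusters of non-immune cells the log2 change of Csf1 turned from -0.75 to 0.29. In T cells, NK cells, monocytes and macrophages, dendritic cells and neutrophils edgeR called 0 genes, with 415, 417, 619 (952 without Control_2), 490 and 738 at an unadjusted p under 0.05 (625, 575, 759, 599 and 480 are expected by chance in every comparison of these classes), and DESeq2 called 1, 3, 3, 6 and 52. The genes of smallest p in T cells were Ndufaf1 (log2 5.22, SE 1.06), Cd81 (-1.53, SE 0.36) and Sh3bgrl2, which was listed at 0 in minP1 and 6.37 ± 2.43 CPM in Control (adjusted p = 0.999). Those in NK cells were Tpgs2 (3.21, SE 0.71), Slc38a10 (-1.04, SE 0.25) and Jmjd8, at 0 in Control and 4.87 ± 5.15 CPM in minP1 (adjusted p = 1). Beside Isg20, monocytes and macrophages had Nkap (0.89, SE 0.18) and Lrrc51, at 0 in Control and 1.05 ± 0.479 CPM in minP1. Dendritic cells had G3bp1 (1.09, SE 0.21), Cd59a (-2.11, SE 0.43) and Wapl (1.25, SE 0.27), with adjusted p = 1.

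Mice given anti-PD-L1 alone were compared with Control mice, and 10 of 22 lists passed in all CD45+ cells. Type I interferon response genes rose, with 25 of 26 above Control and a median log2 change of 0.55 (n = 3 against 3 mice, adjusted p = 2.3e-14, and adjusted p = 0.357 with an estimated correlation). Oasl2, an interferon-induced antiviral protein, had 44.1 ± 0.459 CPM against 24.1 ± 3.34 (log2 0.88, SE 0.24, adjusted p = 0.702). Cholesterol biosynthesis genes fell, with 17 of 18 below (median -0.60, adjusted p = 3.1e-08, and p = 0.357 with an estimated correlation). Msmo1, a sterol demethylating enzyme, had 39.6 ± 6.30 CPM against 78.4 ± 19.7 (log2 -0.98, SE 0.26, adjusted p = 0.645). MHC class II genes rose (13 of 13 above, median 0.52, adjusted p = 4.7e-05, and p = 0.714 with an estimated correlation). Members that passed adjusted over the list alone numbered 4 for interferon, 9 for cholesterol and 0 for MHC class II, against 0 over all genes. Beside these lists neutrophil markers rose (median 0.85, 9 of 10 above, adjusted p = 3.2e-06, and p = 0.176 with an estimated correlation). Conventional DC2 (0.49, 0.00175), conventional DC1 (0.59, 0.000599), B cell (0.92, 0.00991) and eosinophil markers (0.66, 0.00767) rose as well, and fibroblast markers fell (-1.30, 6 of 6 below, 0.000529). With an estimated correlation the B cell markers had an adjusted p = 0.403 and the other 4 an adjusted p = 0.148. Without the non-immune clusters eosinophil (0.0515) and fibroblast markers (0.389) were lost.

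The other 7 lists moved less in CD45+ cells of PDL1 mice. MHC class I (median 0.15, adjusted p = 0.000343), interferon gamma response (0.20, 0.00941), immediate early genes (0.14, 0.0120), T cell exhaustion (0.13, 0.0315) and NF-kB and TLR response (0.09, 0.0315) rose, and cell cycle (-0.24, 0.00134) and mitochondrially encoded transcripts (-0.16, 0.0172) fell. With an estimated correlation immediate early genes had an adjusted p = 0.357 and the other 6 an adjusted p = 0.732. Without the non-immune clusters all but immediate early genes were lost (adjusted p from 0.265 to 0.856). Without PDL1_2 only 4 lists passed, and adjusted p was 0.0533 for MHC class I, 0.137 for interferon gamma, 0.146 for cell cycle, 0.207 for mitochondrial transcripts, 0.538 for exhaustion and 0.755 for NF-kB. Exhaustion was also lost without Control_3 (0.144) or PDL1_3 (0.307), immediate early genes without Control_2 (0.1496) or PDL1_3 (0.0667), and NF-kB without Control_1 (0.0575), Control_2 (0.0537) or Control_3 (0.0672). Mitochondrial transcripts were lost without Control_1 (0.111), Control_3 (0.0672) or PDL1_1 (0.0543).

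Within classes, cholesterol biosynthesis genes fell in monocytes and macrophages of PDL1 mice (median -0.45, 15 of 18 below, adjusted p = 0.000248, and p = 0.980 with an estimated correlation). Of its members 4 passed adjusted over the list alone, against 0 over all genes. It was the 1 list that passed in this class, against 2 without Control_1 or PDL1_1 and 5 without PDL1_2. In dendritic cells MHC class II genes rose (12 of 12 above, median 0.35, adjusted p = 0.000427, and p = 0.637 with an estimated correlation). Type I interferon genes also rose there (0.64, 21 of 26 above, 0.00159, and p = 0.666 with an estimated correlation). That call ended without PDL1_1 (0.101). Cholesterol genes fell (-0.61, 14 of 18 below, 0.0171) and immediate early genes rose (0.26, 0.0404) in dendritic cells, each p = 0.637 with an estimated correlation. The first ended without Control_1 (0.184) or Control_3 (0.0994), and the second without Control_2 (0.149), Control_3 (0.164) or PDL1_3 (0.361). Plasmacytoid DC markers fell in this class (-0.61, 8 of 8 below, 0.00451) and conventional DC1 markers rose (0.55, 0.0168), each p = 0.434 with an estimated correlation. Both ended without high doublet scores (0.110 and 0.0955), as did MHC class II (0.0740). Dendritic cells had 8 lists without PDL1_3, against 4.

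In T cells of PDL1 mice immediate early genes, which are transcribed within minutes of stimulation or of tissue dissociation, rose (17 of 20 above, median 0.38, adjusted p = 0.000783, and p = 0.280 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, had 944 ± 48.6 CPM against 552 ± 103 (log2 0.77, SE 0.15, adjusted p = 0.861). The call ended without PDL1_2 (0.0549). Type I interferon genes rose in T cells (0.38, 18 of 26 above, 0.0412, and p = 0.990 with an estimated correlation) and in NK cells (0.24, 18 of 23 above, 0.0101, and p = 0.453 with an estimated correlation). The T cell call ended without Control_2 (0.155), Control_3 (0.159), PDL1_1 (0.855) or PDL1_2 (0.257), and the NK call without Control_2 (0.0650) or PDL1_1 (0.548). Neutrophil markers fell in T cells (-0.85, 9 of 10 below, 0.0120, and p = 0.508 with an estimated correlation), except without high doublet scores (0.198). In neutrophils interferon gamma response (0.97, 18 of 23 above), type I interferon (0.90, 20 of 26) and NF-kB genes (0.70, 23 of 26) rose and cell cycle genes fell (-0.34), each with adjusted p = 0.0356 from 2 Control mice. Each had an adjusted p = 0.698 with an estimated correlation, and 0 passed without PDL1_1 and 1 without PDL1_2. The loss without PDL1_1 was at 0.131 for interferon gamma and 0.177 for the other 3, and that without PDL1_2 at 0.241 for all but cell cycle (0.351). T cell markers (-0.88, 0.00493) and CD8 T cell markers (-1.40, 0.00633) fell in the neutrophils, each p = 0.683 with an estimated correlation.

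No single gene passed between PDL1 and Control. Over all CD45+ cells edgeR called 0 genes, 1211 had an unadjusted p under 0.05 where 920 are expected by chance, and DESeq2 called 48. The 1211 became 2045 without PDL1_1, 844 without PDL1_2 (957 expected) and 847 without Control_1 (958 expected), and counting cells gave 584 (618 expected). The 3 genes of smallest p (each adjusted p = 0.571) were S100a9, an abundant calcium-binding protein of neutrophils, at 522 ± 169 CPM against 203 ± 24.98 (log2 1.36, SE 0.25), Pagr1a (0.69, SE 0.13) and Aif1l at 0.198 ± 0.170 CPM against 3.42 ± 1.30. In T cells, NK cells, monocytes and macrophages, dendritic cells and neutrophils edgeR called 0 genes, with 588, 560, 807, 537 and 683 at an unadjusted p under 0.05, and DESeq2 called 11, 3, 5, 6 and 39. After Fos, T cells had Mpeg1 (-2.71, SE 0.55, adjusted p = 0.861) and Slamf7 (2.12, SE 0.47, adjusted p = 0.870). NK cells had Cd151 (4.61, SE 1.12), Zfp770 at 0 in PDL1 and 21.2 ± 11.4 CPM in Control, and Jmjd8 at 8.35 ± 4.62 CPM in PDL1 and 0 in Control (adjusted p = 0.993). Monocytes and macrophages had Zbtb7b (1.15, SE 0.20), Clk4 (-0.71, SE 0.13) and Zfp839 (2.69, SE 0.51), with adjusted p = 0.534. Dendritic cells had Lair1, an inhibitory collagen receptor (-1.38, SE 0.29), Fuca1 (1.12, SE 0.25) and Rundc3b, at 0 in Control and 15.7 ± 12.4 CPM in PDL1 (adjusted p = 1.000).

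Mice given both agents were compared with Control mice, and 13 of 22 lists passed in all CD45+ cells. Cholesterol biosynthesis genes fell, with 18 of 18 below Control and a median log2 change of -0.71 (n = 4 against 3 mice, adjusted p = 4.4e-12, and adjusted p = 0.358 with an estimated correlation). Sqle, a rate-limiting enzyme of sterol synthesis, had 19.8 ± 6.25 CPM against 41.7 ± 5.81 (log2 -1.07, SE 0.25). Cell cycle genes fell (30 of 30 below, median -0.38, adjusted p = 1.2e-10), and MHC class II (13 of 13 above, 0.58, 1.3e-05) and type I interferon genes (24 of 26, 0.32, 1.5e-06) rose, each adjusted p = 0.403 with an estimated correlation. Genes of the NF-kB and TLR inflammatory response rose (24 of 29 above, median 0.36, adjusted p = 1.5e-06, and p = 0.358 with an estimated correlation). Cxcl2, a chemokine that draws neutrophils, had 2052 ± 554 CPM against 1179 ± 217 (log2 0.80, SE 0.24). Members that passed adjusted over the list alone numbered 15 for cholesterol, 5 for cell cycle, 5 for NF-kB, 1 for type I interferon and 0 for MHC class II, against 0 over all genes. Beside these, neutrophil markers rose (median 0.93, 9 of 10 above, adjusted p = 9.7e-08, and p = 0.185 with an estimated correlation). Eosinophil (0.81, 0.00119), conventional DC2 (0.48, 0.0189), monocyte (0.26, 0.0187) and CD4 T cell markers (0.38, 0.0443) rose, and fibroblast markers fell (-1.39, 6 of 6 below, 0.000107). These had adjusted p = 0.152, 0.367, 0.5002, 0.598 and 0.152 with an estimated correlation. Without the non-immune clusters only neutrophil and eosinophil markers of these passed, and the median of type I interferon was 0.11 (adjusted p = 0.0466). CD4 T cell markers were also lost without the mixed cluster (0.0527) or high doublet scores (0.0716).

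**Figure D3:**
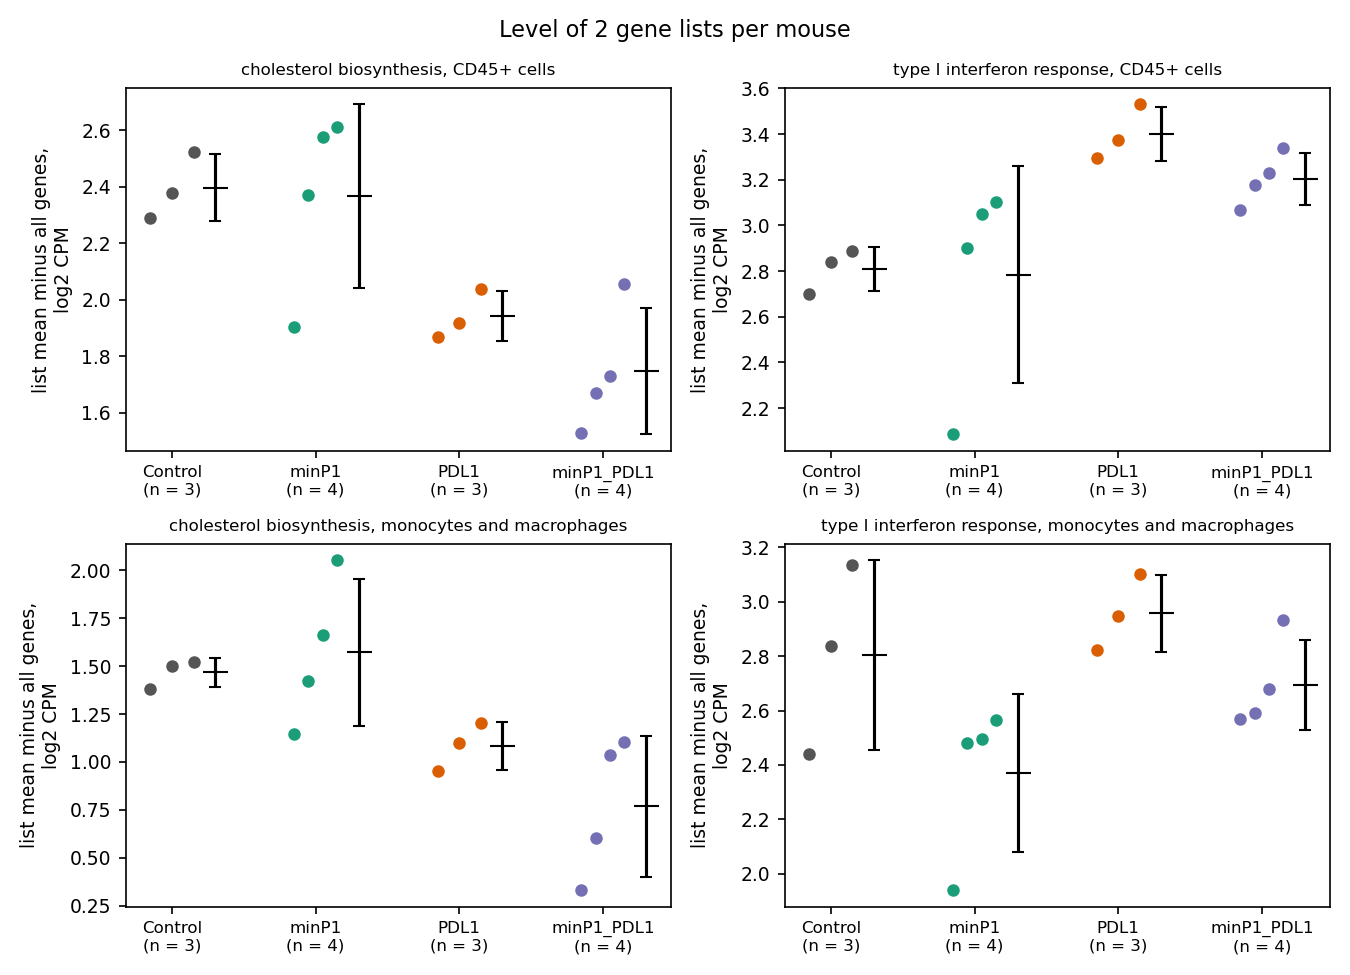
Mean level of 2 gene lists in each mouse, as log2 CPM of the list minus that of all genes (y axis), in all CD45+ cells and in monocytes and macrophages, with 1 dot per mouse and the group mean and SD as the bar beside the dots. In CD45+ cells the cholesterol list averaged 2.40 in Control, 2.37 in minP1, 1.94 in PDL1 and 1.75 in minP1_PDL1, and minP1_1 lay at 2.09 in type I interferon where the other minP1 mice lay between 2.90 and 3.10.

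The other 8 lists also passed between minP1_PDL1 and Control. Interferon gamma response genes rose (22 of 25 above, median 0.29, adjusted p = 6.4e-05, and p = 0.455 with an estimated correlation), and mitochondrially encoded transcripts fell (-0.18, 0.000873, and p = 0.403 with an estimated correlation). T cell exhaustion genes rose (0.22, 0.00416, and p = 0.474 with an estimated correlation), except without minP1_PDL1_2 (0.111). Immediate early genes rose (0.16, 0.00438, and p = 0.358 with an estimated correlation), except without Control_2 (0.0590). MHC class I genes rose (0.13, 0.00864, and p = 0.654 with an estimated correlation), except without Control_2 (0.0590), minP1_PDL1_3 (0.0585) or minP1_PDL1_4 (0.112). Suppressive macrophage genes rose (0.32, 0.0107, and p = 0.403 with an estimated correlation), except without Control_2 (0.0547), minP1_PDL1_1 (0.0523) or minP1_PDL1_3 (0.0649). The regulatory T cell programme rose (0.23, 0.0122, and p = 0.497 with an estimated correlation), except without Control_2 (0.0630) or minP1_PDL1_2 (0.104). Oxidative phosphorylation genes fell (-0.08, 0.0127, and p = 0.403 with an estimated correlation), except without Control_2 (0.0590) or minP1_PDL1_1 (0.0504). Without the non-immune clusters MHC class I (0.694), exhaustion (0.434), regulatory (0.773) and suppressive genes (0.185, and 0.182 without the mixed cluster) ended too.

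In monocytes and macrophages of minP1_PDL1 mice cholesterol genes fell (18 of 18 below, median -0.73, adjusted p = 5.8e-11) as did cell cycle genes (30 of 30, -0.44, 4.5e-11), each p = 0.418 with an estimated correlation. Insig1, a sterol-regulated gene, had 41.2 ± 5.21 CPM against 70.4 ± 8.59 (log2 -0.77, SE 0.17). Adjusted over the list alone, 7 cholesterol and 6 cell cycle members passed, against 0 over all genes. MHC class II genes rose (12 of 13 above, 0.36, 0.0142, and p = 0.856 with an estimated correlation), with an adjusted p of 0.152 once the replicate number was added to the model. Without Control_1 (0.134), minP1_PDL1_3 (0.126) or minP1_PDL1_4 (0.259) that call ended, and 7 lists in place of 3 passed without minP1_PDL1_1 or minP1_PDL1_2. In NK cells cholesterol genes fell (-0.48, 16 of 18 below, 0.0121, and p = 0.304 with an estimated correlation), except without Control_3 (0.146), minP1_PDL1_2 (0.0613), minP1_PDL1_3 (0.0600) or high doublet scores (0.175). It was the 1 NK list, against 2 without Control_2 or minP1_PDL1_1.

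T cells of minP1_PDL1 mice held the 1 gene that passed. Fos had 1147 ± 171 CPM against 552 ± 103 in Control, 803 ± 123 in minP1 and 944 ± 48.6 in PDL1 (log2 against Control 1.06, SE 0.15, adjusted p = 0.0233). With fewer than 3 genes past the threshold it is given as a value, with Pkp4 (-1.35, SE 0.25, adjusted p = 0.335) and Pacsin2 (-1.83, SE 0.37, adjusted p = 0.552). Immediate early genes rose with it (17 of 20 above, median 0.42, adjusted p = 3.3e-06, and p = 0.141 with an estimated correlation), 6 of them adjusted over the list alone and 1 over all genes. Cell cycle genes fell (-0.37, 26 of 30 below, 0.00647, and p = 0.772 with an estimated correlation), except without Control_1 (0.0542) or minP1_PDL1_3 (0.576). Costimulatory ligand genes fell (-0.71, 9 of 10 below, 0.0337, and p = 0.170 with an estimated correlation), except without Control_1 (0.0624), Control_2 (0.0627), Control_3 (0.0513), minP1_PDL1_1 (0.111), minP1_PDL1_4 (0.109) or high doublet scores (0.0572). Interferon gamma genes rose (0.16, 0.0480, and p = 0.682 with an estimated correlation), except without Control_1 (0.0624), Control_2 (0.207), Control_3 (0.0709), minP1_PDL1_2 (0.0730), minP1_PDL1_3 (0.216), minP1_PDL1_4 (0.0957) or high doublet scores (0.0878). CD4 T cell markers rose beside them (0.73, 5 of 5 above, 0.0412, and p = 0.345 with an estimated correlation), except without high doublet scores (0.177). The Fos call ended without Control_2 (0.358), Control_3 (0.199), minP1_PDL1_1 (0.0518), minP1_PDL1_3 (0.101) or minP1_PDL1_4 (0.0969), without the cell filter (0.0978), with the replicate number in the model (log2 1.03, 0.244) and when cells rather than reads were counted (0.39, 0.998).

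In dendritic cells of minP1_PDL1 mice 8 lists passed. MHC class II genes rose (12 of 12 above, median 0.31, adjusted p = 0.00179, and p = 0.484 with an estimated correlation), with Cd74 at 8366 ± 1259 CPM against 6805 ± 324. Complement genes (-0.52, 15 of 17 below, 0.00179), cholesterol genes (-0.58, 16 of 18, 0.00179), suppressive macrophage genes (-0.76, 18 of 23, 0.0159) and myeloid-recruiting chemokines (-0.90, 11 of 13, 0.0148) fell, each p = 0.415 with an estimated correlation. Fn1, fibronectin, had 76.5 ± 10.996 CPM against 405 ± 72.2 (log2 -2.40, SE 0.42, adjusted p = 0.345). Macrophage markers fell with them (11 of 11 below, -1.24, 0.00233) and monocyte markers in 9 of 9 (-0.32, 0.0472), each p = 0.470 with an estimated correlation. Hypoxia (-0.32, 0.0148), cytotoxic effector (-0.53, 0.0290) and cell cycle genes (0.31, 0.0282) passed with adjusted p = 0.639, 0.639 and 0.815 with an estimated correlation. Without minP1_PDL1_2 no list passed, at adjusted p = 0.0592 for MHC class II, complement and cholesterol, 0.110 for cell cycle, 0.149 for suppressive, hypoxia and cytotoxic genes, and 0.203 for the chemokines. Without Control_2 the chemokines (0.0801), suppressive (0.187), cytotoxic (0.0959) and cell cycle genes (0.0723) were lost, and without Control_3 the chemokines (0.0845), hypoxia (0.0549), cytotoxic and cell cycle genes (both 0.475). Hypoxia was also lost without Control_1 (0.203) or minP1_PDL1_4 (0.0678), cytotoxic genes without minP1_PDL1_4 (0.0590), and cell cycle without minP1_PDL1_1 (0.571) or minP1_PDL1_4 (0.227). With high doublet scores left out MHC class II (0.312), cytotoxic (0.333) and suppressive genes (0.422) and macrophage (0.875) and monocyte markers (0.0759) were lost, and the medians of the chemokines and complement turned to 0.09 (adjusted p = 0.922) and 0.12 (0.939).

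In neutrophils of minP1_PDL1 mice, set against 2 Control mice, 7 lists passed. Immediate early genes rose (18 of 20 above, median 0.81, adjusted p = 0.00540, and p = 0.0983 with an estimated correlation), as did NF-kB genes (22 of 26, 0.75, 0.00540, and p = 0.563 with an estimated correlation). Adjusted over the list alone 5 members of each passed, against 0 over all genes. Myeloid-recruiting chemokines (1.19, 12 of 12 above, 0.0171) and interferon gamma genes (1.00, 20 of 23, 0.0129) rose, and cell cycle (-0.51, 23 of 29 below, 0.00540) and oxidative phosphorylation genes (-0.58, 20 of 25, 0.0129) fell, each p = 0.563 with an estimated correlation. Type I interferon genes rose (0.57, 0.0392, and p = 0.570 with an estimated correlation). That call ended without minP1_PDL1_2 (0.121), interferon gamma without minP1_PDL1_4 (0.0537), and the chemokines without minP1_PDL1_3 (0.0612). T cell markers (-1.10, 0.0125) and CD8 T cell markers (-1.66, 0.0125) fell beside them, each p = 0.844 with an estimated correlation, and these fell in minP1 too (-0.90, 0.0437 and -1.71, 0.00228, with adjusted p = 0.713 and 0.621 with an estimated correlation). The 3 genes of smallest p, in each comparison with Control, were Mtmr6 (58.0 ± 22.4 CPM in minP1, 92.0 ± 13.9 in PDL1, 93.5 ± 41.3 in minP1_PDL1), Gab2 (58.1 ± 13.7, 59.7 ± 27.0, 69.4 ± 24.0) and Rasgrp4 (63.9 ± 30.4, 74.8 ± 61.7, 94.2 ± 33.2). All were at 0 in the Control neutrophils, which numbered 13 cells in Control_2 and 19 in Control_3, and their smallest adjusted p was 0.0762.

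Outside Fos no single gene passed between minP1_PDL1 and Control. In all CD45+ cells edgeR called 0 genes, 1915 had an unadjusted p under 0.05 against 920 expected by chance, and DESeq2 called 147. The 1915 became 1228 without Control_1 (958 expected), 1416 without the non-immune clusters (867 expected) and 2692 without minP1_PDL1_1. S100a9 had the smallest p, at 600 ± 167 CPM against 203 ± 24.98 (log2 1.56, SE 0.24, adjusted p = 0.264), and passed once the cluster of mixed lineage was left out or genes in under 10% of cells were dropped. Slc7a11, the cystine transporter, followed at 46.6 ± 4.06 CPM against 17.3 ± 1.31 (log2 1.43, SE 0.23, adjusted p = 0.264). The neutrophil share also rose here, and CD45+ sums do not separate this. In NK cells, monocytes and macrophages, dendritic cells and neutrophils edgeR called 0 genes, with 571, 1104, 630 and 822 at an unadjusted p under 0.05, and DESeq2 called 7, 41, 14 and 83. T cells had 652 at that p and 7 by DESeq2. The NK genes of smallest p were Cd151 (5.57, SE 1.14), Pxdc1 (-2.66, SE 0.56) and Jmjd8, at 12.9 ± 5.95 CPM against 0 (adjusted p = 0.588). Monocytes and macrophages had Rpl32 (-0.21, SE 0.04), a ribosomal protein gene whose log2 change was 0.03 when cells were counted, the lysosomal protease Ctsh (0.56, SE 0.11) and Rit1 (0.87, SE 0.18), with adjusted p = 0.457. After Fn1, dendritic cells had Timeless (-2.30, SE 0.51) and Rundc3b, at 9.51 ± 10.2 CPM against 0 (adjusted p = 0.7099). Without the low-count filter edgeR called 38 genes in neutrophils.

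Mice given both agents were compared with mice given anti-PD-L1 alone, which isolates the addition of minP1. Type I interferon genes in all CD45+ cells were lower with both agents (25 of 26 below, median log2 -0.14, n = 4 against 3 mice, adjusted p = 0.00345) as were cell cycle genes (28 of 30, -0.17, 0.000398), while NF-kB genes rose (24 of 29 above, 0.26, 0.00324), as did myeloid-recruiting chemokines (0.28, 0.0461), and oxidative phosphorylation genes fell (-0.05, 0.0492). All 5 had adjusted p = 0.786 with an estimated correlation, and 0 members passed adjusted over the list alone. No list passed without PDL1_1, at 0.0820 for type I interferon, 0.396 for NF-kB, 0.123 for the chemokines and for cell cycle, and 0.316 for oxidative phosphorylation. Type I interferon was also lost without PDL1_2 (0.0599), NF-kB and the chemokines without minP1_PDL1_3 (both 0.0871), and cell cycle without minP1_PDL1_3 (0.438). The chemokines were lost without PDL1_3 (0.102), minP1_PDL1_1 (0.709) or minP1_PDL1_4 (0.0664), and oxidative phosphorylation without any minP1_PDL1 mouse (0.0739, 0.0624, 0.0921 and 0.0531). Type I interferon and the chemokines were lost without the mixed cluster (both 0.233) or high doublet scores (0.176 and 0.159), oxidative phosphorylation without those scores (0.176), and the chemokines without the non-immune clusters (0.0584).

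Type I interferon genes were also lower with both agents than with anti-PD-L1 alone in 4 classes. The median was -0.56 in T cells (23 of 26 below, adjusted p = 0.000371), -0.47 in NK cells (18 of 23, 0.0116), -0.21 in monocytes and macrophages (24 of 26, 0.00127) and -0.61 in dendritic cells (21 of 26, 0.00138). With an estimated correlation these had adjusted p = 0.719, 0.894, 0.751 and 0.888. Rtp4, an interferon-induced chaperone, had 11.9 ± 4.25 CPM against 73.0 ± 63.9 in NK cells (log2 -2.62, SE 0.55, adjusted p = 0.827). Without PDL1_1 the calls in T cells (0.254), NK cells (0.715) and dendritic cells (0.102) ended, as did that in monocytes and macrophages without PDL1_3 (0.128) and that in NK cells without minP1_PDL1_2 (0.0708) or minP1_PDL1_4 (0.0985). Cell cycle genes fell in monocytes and macrophages (-0.37, 25 of 30 below, 2.5e-07, and p = 0.751 with an estimated correlation), 7 of them adjusted over the list alone. There NF-kB genes rose (0.21, 0.0244) and cholesterol genes fell (-0.18, 0.0280), both p = 0.751 with an estimated correlation. NF-kB was lost without PDL1_1 (0.478), PDL1_3 (0.128) or minP1_PDL1_3 (0.329), and cholesterol without PDL1_2 (0.0659), PDL1_3 (0.128), minP1_PDL1_3 (0.338) or minP1_PDL1_4 (0.0720). Without the mixed cluster type I interferon (0.999, with a median of 0.06), cholesterol (0.620) and NF-kB (0.0576) were lost in this class, and without high doublet scores the first 2 (both 0.501), and type I interferon in dendritic cells (0.135).

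In dendritic cells NF-kB (-0.49, 22 of 26 below, 0.00535), myeloid-recruiting chemokine (-0.76, 12 of 13, 0.00535) and complement genes (-0.25, 14 of 17, 0.0113) fell with both agents against anti-PD-L1 alone, each p = 0.771 with an estimated correlation. Macrophage markers fell with them (-1.15, 10 of 11, 0.00365) and plasmacytoid DC markers rose (0.51, 8 of 8, 0.00365), both p = 0.642 with an estimated correlation. NF-kB was lost without PDL1_2 (0.0721) or minP1_PDL1_1 (0.175), the chemokines without PDL1_2 (0.131) or minP1_PDL1_2 (0.292), and complement without PDL1_1 (0.102), PDL1_2 (0.0526), minP1_PDL1_1 (0.127) or minP1_PDL1_2 (0.292). Without high doublet scores the chemokines (0.473), complement (0.770) and both markers (0.650 and 0.433) were lost. In T cells cell cycle genes (-0.35, 26 of 30 below, 0.0243) and costimulatory ligands (-0.95, 7 of 10, 0.0498) fell, with adjusted p = 0.839 and 0.425 with an estimated correlation. Cell cycle was lost without PDL1_1 (0.436), PDL1_2 (0.0530) or minP1_PDL1_3 (0.879), and costimulation without PDL1_1 (0.254), PDL1_2 (0.102), PDL1_3 (0.0623), minP1_PDL1_1 (0.185), minP1_PDL1_3 (0.0569), minP1_PDL1_4 (0.185) or high doublet scores (0.121). NK cells, with 1 list, had 3 without PDL1_3. Neutrophils had 0 lists by camera, and 2 without PDL1_2.

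No single gene passed between minP1_PDL1 and PDL1. By edgeR 0 genes passed in all CD45+ cells, 776 had an unadjusted p under 0.05 (920 expected), and DESeq2 called 3. The genes of smallest p were Slc25a37, the mitochondrial iron importer (0.50, SE 0.10), Zfp763 (4.46, SE 0.93) and Cep78 (-1.43, SE 0.30), each with adjusted p = 0.999. In T cells, NK cells, monocytes and macrophages, dendritic cells and neutrophils edgeR called 0 genes, with 704, 652, 921, 573 and 343 at an unadjusted p under 0.05 (the last 559 without cells of doublet score over 0.5), and DESeq2 called 5, 2, 11, 2 and 1. Gda, guanine deaminase, had 57.1 ± 6.69 CPM against 172 ± 33.0 in dendritic cells (log2 -1.59, SE 0.24, adjusted p = 0.0528), and 2 genes passed there without PDL1_2. It was followed by Ergic1 (1.70, SE 0.39) and Lrrc57 (2.04, SE 0.47). T cells had Stx6 (1.47, SE 0.30), Oxa1l (-1.17, SE 0.25) and Fam43a (-5.63, SE 1.23), with adjusted p = 0.797. Beside Rtp4, NK cells had Sept2 (-1.11, SE 0.24) and Zfp808, at 0 in minP1_PDL1 and 14.6 ± 1.57 CPM in PDL1. Monocytes and macrophages had Rab5if (0.47, SE 0.09), Il2 at 6.90 ± 8.49 CPM against 0.0220 ± 0.0380, and Mms22l (1.71, SE 0.32), with adjusted p = 0.475. Neutrophils had Igf1r (2.91, SE 0.64), Penk at 0 against 190 ± 289 CPM, and Nup85 at 0 against 23.4 ± 6.69 CPM.

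Mice given both agents were compared with mice given minP1 alone, which isolates the addition of the antibody, and 13 of 22 lists passed in all CD45+ cells. Cholesterol biosynthesis genes fell (18 of 18 below, median log2 -0.44, n = 4 against 4 mice, adjusted p = 1.0e-14, and adjusted p = 0.168 with an estimated correlation), with Idi1, of the isoprenoid steps, at 16.3 ± 4.11 CPM against 33.8 ± 8.80 (log2 -1.05, SE 0.21, adjusted p = 0.391). Type I interferon genes rose (26 of 26 above, 0.36, 2.3e-12, and p = 0.319 with an estimated correlation). The level of this list was 2.09 in minP1_1, 2.90 to 3.10 in the other minP1 mice and 3.07 to 3.34 in minP1_PDL1. NF-kB genes rose (24 of 29 above, 0.24, 1.7e-07, and p = 0.269 with an estimated correlation). Adjusted over the list alone 10 cholesterol, 3 interferon and 4 NF-kB members passed, against 0 over all genes. Neutrophil markers rose beside them (0.67, 9 of 10, 1.1e-06, and p = 0.762 with an estimated correlation). Interferon gamma (0.28, 2.9e-06), MHC class I (0.14, 0.000301), immediate early (0.16, 0.000538) and regulatory T cell programme genes (0.22, 0.00151) rose and oxidative phosphorylation genes fell (-0.08, 0.00129). With an estimated correlation these had adjusted p = 0.535, 0.598, 0.168, 0.541 and 0.326. MHC class II (0.23, 0.0369), exhaustion (0.08, 0.0279) and myeloid chemokine genes (0.21, 0.0279) rose, and cell cycle (-0.15, 0.000291) and mitochondrially encoded transcripts (-0.09, 0.00872) fell, with adjusted p = 0.713, 0.647, 0.613, 0.613 and 0.598 with an estimated correlation. Each of these 5 ended without some mouse: MHC class II without minP1_1 (0.420), minP1_PDL1_2 (0.0985), minP1_PDL1_3 (0.252) or minP1_PDL1_4 (0.575), exhaustion without minP1_1 (0.0516), minP1_2 (0.120), minP1_PDL1_2 (0.582) or minP1_PDL1_3 (0.0962), the chemokines without minP1_1 (0.196) or minP1_PDL1_1 (0.837), cell cycle without minP1_PDL1_3 (0.532), and mitochondrial transcripts without minP1_PDL1_4 (0.0779). Without the mixed cluster or high doublet scores MHC class II (0.178 and 0.460), exhaustion (0.290 and 0.183) and the chemokines (0.115 and 0.0616, and 0.0710 without the non-immune clusters) ended too.

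No single gene passed between minP1_PDL1 and minP1 in all CD45+ cells, where edgeR called 0 genes, 1106 had an unadjusted p under 0.05 (920 expected), and DESeq2 called 43. Slc48a1, a heme transporter (log2 0.79, SE 0.14), Plau, urokinase (-0.93, SE 0.17), and Dpysl2 (-0.50, SE 0.09) had the smallest p (each adjusted p = 0.371). The interaction asks whether the change with minP1 differed with and without the antibody. By edgeR 0 genes passed for it, 826 had an unadjusted p under 0.05 (920 expected, and 1357 without PDL1_1), and DESeq2 called 10. Its genes of smallest p were Hpgds, a prostaglandin D2 synthase (-1.72, SE 0.32), Pagr1a (-0.86, SE 0.17) and Dpysl2 (-0.66, SE 0.14), each with adjusted p = 1.000.

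Genes of the axis under treatment did not pass in all CD45+ cells in any comparison by edgeR. Cd274, which encodes PD-L1, had 144 ± 8.44 CPM in Control, 167 ± 33.6 in minP1, 194 ± 57.7 in PDL1 and 227 ± 75.7 in minP1_PDL1, a log2 change of 0.66 against Control (SE 0.26, adjusted p = 0.417). Pdcd1, which encodes PD-1, had 37.8 ± 3.39, 34.3 ± 4.56, 34.95 ± 2.24 and 34.1 ± 10.7 CPM. Hmgn1 had 170 ± 10.2, 130 ± 31.1, 128 ± 41.8 and 110 ± 21.3 CPM (log2 -0.63 with both agents, SE 0.21, adjusted p = 0.386), and Tlr4, a receptor reported for HMGN1, 36.1 ± 8.30, 47.5 ± 6.92, 41.0 ± 7.14 and 45.7 ± 11.2. The effector genes Ifng, Gzmb and Prf1 had log2 changes of 0.05, -0.05 and -0.16 with both agents, with Gzmb at 1109 ± 45.5, 1151 ± 173, 1112 ± 299 and 1074 ± 136 CPM. Cd8a (-0.10) and Foxp3 (0.27) had adjusted p = 0.882 and 0.694. The chemokine genes Cxcl9 and Cxcl10, ligands of a receptor on activated T cells, had 374 ± 170 and 244 ± 92.0 CPM with both agents against 341 ± 77.3 and 215 ± 29.1. The dendritic cell genes Il12b (0.56, SE 1.35, and -1.83 without minP1_PDL1_2), Ccr7 (-0.41, SE 0.25), Cd80 (-0.08, SE 0.25) and Cd86 (0.31, SE 0.23) had adjusted p from 0.606 to 0.940. In dendritic cells Cd80, a ligand of CD28, had 58.7 ± 15, 37.6 ± 21.4, 36.2 ± 11.9 and 19.3 ± 5.20 CPM (log2 -1.60 with both agents, SE 0.44, adjusted p = 0.863).

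Precision differed by class. The biological coefficient of variation between mice was 0.434 in all CD45+ cells and in monocytes and macrophages, 0.616 in T cells, 0.676 in NK cells, 0.718 in dendritic cells and 1.09 in neutrophils. Of 101 list calls, 0 held with an estimated correlation (smallest adjusted p = 0.0983). With the replicate number in the model 94 held, and 31 without each mouse in turn. Neutrophil calls had no Control mouse or high doublet scores left out. Divisions of these mice into groups of these sizes numbered 35 with the real one. In CD45+ cells 5 gave at least 13 lists for minP1_PDL1 against Control and 5 against minP1. Members named beside a list were chosen after their values were seen. The lists for naive T cells, T cell-recruiting chemokines and the unfolded protein response passed in no comparison.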

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

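Of the tests in this part, those of the shallow barcodes, of free RNA from non-immune cells and of S100a8 in the mixed cluster had predictions written before their values were seen, and all others, the divisions of the mice included, were chosen only after the result was seen.

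Single mice lay far from the other 3 of their group in 5 of 96 groups of 4 tested, where chance alone gives about 1 in 20. Gamma delta T cells took 3.49% of cells in minP1_PDL1_3 against 0.911% to 1.26% in the others, and mature DC (37 cells in all, 70.3% over a doublet score of 0.5) took 0.546% in minP1_PDL1_4 against 0.1795% to 0.205%. In all CD45+ cells Il12b, a subunit of IL-12, had 105 CPM in minP1_PDL1_2 against 0.258 to 11.03. Cd80 had 12.2 CPM in minP1_PDL1_1 against 20.5 to 21.5, and S100a8 had 289 in minP1_3 against 164 to 173. The effect of minP1 with and without anti-PD-L1 differed by -0.612 points for mature DC (exact permutation p = 0.0335, adjusted p = 0.402) and by -0.995 points for an unnamed cluster of 53 cells with Ifng and Batf, all over a doublet score of 0.5 and with Trac, Ncr1 and Foxp3 in 94.3%, 62.3% and 43.4% (exact permutation p = 0.0294, adjusted p = 0.402), among 24 such interactions tested.

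The higher neutrophil share of treated mice was weighed against 2 technical readings. Other barcodes below the median neutrophil (13302.5 counts) took 11.7% ± 1.33 of cells in Control and 12.1% ± 2.38 in the 11 treated mice. PDL1 had 9.66% and minP1 13.6%, and the ratio was 1.035 (neutrophils 2.95). Median counts per neutrophil were 16174 in Control and 12458 to 14053 in treated groups, so a barcode threshold was left open. Without the 2 non-immune clusters the adjusted permutation p was 0.0288, which argues against a smaller denominator. Anti-PD-L1 may be the cause, at 8.86% ± 1.68 in the 7 mice given it and 4.06% ± 1.83 in 7 others. The exact permutation within minP1 strata left this undecided (adjusted p = 0.0686). Flow cytometry of blood and tumour in larger groups could separate recruitment from survival.

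Lower cholesterol biosynthesis transcripts in mice given anti-PD-L1 were weighed next. Without the 2 clusters of non-immune cells the median log2 change of minP1_PDL1 against Control was -0.597, which argues against those cells as the source. Free RNA of such cells could bring at most 0.870% of the list's counts in monocytes and macrophages (from Sparc, at 1132 CPM in non-immune cells and 5.04 in that class), which argues against it too. The antibody may be the cause, with a level of 1.83 ± 0.20 in 7 mice against 2.38 ± 0.24 in 7 (exact permutation p = 0.00286 within minP1 strata, adjusted p = 0.0314 over the lists of that cell set), although over all 402 such tests the adjusted p was 0.164. The list calls themselves did not hold with an estimated correlation, and sterol measurements on sorted macrophages could test the reading.

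A macrophage cluster of 1250 cells carried lymphocyte transcripts at a median of 119556 counts per cell, with Lyz2 and Trac together in 82.4% of cells and Lyz2 and Ncr1 in 54.8%, against 26.7% and 11.3% of 772 other macrophages at 40784 counts. T cell and NK cell scores ran against each other over its cells (Spearman rho -0.241), which argues against RNA free in the pooled suspension. Pairs of cells of the same mouse expected from the 141 hashtag doublets came to 11.05, or 0.980% of its 1128 cells of doublet score over 0.5, which argues against random co-capture. Cells of 1 mouse held together before pooling might explain it, but the share of its cells with S100a8 followed the mouse's neutrophil share only at r = 0.491 (permutation p = 0.0762, rho 0.534, p = 0.0526), 0.418 without the 2 farthest mice and 0.323 within groups. Other macrophages had r = 0.511 (permutation p = 0.0601), so the test did not decide, and no biological explanation was tested.

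Divisions of the same mice into 2 groups of the same sizes, the real division included, were counted. A real count of 0 genes is met by every division, so that these 35 of 35 test nothing and only the highest other count informs. By edgeR this was so in all CD45+ cells for minP1 against Control (highest other 0), minP1_PDL1 against Control (1), minP1_PDL1 against PDL1 (41) and minP1_PDL1 against minP1 (1), and in all 100 drawn for the interaction (0). The 41 genes came from minP1_PDL1_2, minP1_PDL1_3 and minP1_PDL1_4 with PDL1_2 against the rest. Those mice had 25, 14, 27 and 13 cells of the larger non-immune cluster, and the rest (minP1_PDL1_1, PDL1_1 and PDL1_3) 61, 66 and 32, a structure of the samples. DESeq2's 147 genes for minP1_PDL1 against Control were matched in 3 of 35 divisions, with 869 for minP1_PDL1_1 and the 3 Control mice (61, 66, 51 and 54 such cells) against the rest (25, 14 and 27). Whether these cells account for the 2 divisions was not tested. A real 0 gave 35 of 35 in T cells for minP1 against Control (0) and minP1_PDL1 against PDL1 (2), in NK cells for the 3 comparisons other than PDL1 against Control (0, 1 and 0), in monocytes and macrophages (0, 5 and 5), in dendritic cells (0, 1 and 1), and in neutrophils for minP1_PDL1 against PDL1 (1). The 1 gene of T cells between minP1_PDL1 and Control was reached in 1 of 35 divisions, the real one, with 0 as the highest other. For PDL1 against Control the 10 divisions are too few, with 0 genes in the real groups and 0 as the highest other in all 5 sets.

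Where 35 divisions of the mice could be made, others also reached each number of passing lists. In all CD45+ cells 29 of 35 divisions gave at least the 3 of minP1 against Control (highest other 11), 5 the 13 of minP1_PDL1 against Control (16), 27 the 5 of minP1_PDL1 against PDL1 (15) and 5 the 13 of minP1_PDL1 against minP1 (16). In T cells the divisions numbered 35 for a real count of 0 (6), 3 for 4 (4) and 4 for 3 (3), in the order minP1 against Control, minP1_PDL1 against Control and minP1_PDL1 against PDL1. In that order NK cells had 8 for 2 (5), 11 for 1 (3) and 14 for 1 (5), monocytes and macrophages 5 for 7 (9), 30 for 3 (15) and 30 for 4 (16), and dendritic cells 26 for 1 (4), 3 for 8 (8) and 19 for 4 (9). Neutrophils had 35 for 0 (6) in minP1_PDL1 against PDL1. Against the 2 Control mice of that class the 7 lists of minP1_PDL1 were reached by 1 of 15 divisions, the real one, with 5 as the highest other, and the 0 of minP1 by all 15 (7), but 15 are too few. For PDL1 against Control 10 divisions are too few, with 10 lists in the real groups and 10 as the highest other in CD45+ cells, 2 and 2 in T cells, 1 and 3 in NK cells, 1 and 10 in monocytes and macrophages, 4 and 6 in dendritic cells, and 4 and 7 in neutrophils. Chance was thus not excluded for the list counts with 35 divisions. The other divisions still part treated from untreated mice to some degree.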

How the results depend on the processing

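The alternatives that leave out clusters or cells of doublet score over 0.5, keep genes in at least 10% of cells or count cells were chosen after the data had been seen. The cause of a change was not tested unless fewer mice or genes explain it. With 3 or 4 mice per group, reads that were not collapsed and a biological coefficient of variation from 0.434 to 1.09, changes of 2-fold in single genes were mostly below what the tests can show. At least 20 cells per mouse gave no value for neutrophils.

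Counts of genes were the same under RLE normalization in 26 of 26 comparisons, at resolution 0.5 in 20 of 20 and with at least 20 cells in 16 of 16. DESeq2 moved all 26, to 38, 48, 147, 3, 43 and 10 genes in CD45+ cells (minP1, PDL1 and minP1_PDL1 against Control, minP1_PDL1 against PDL1 and against minP1, and the interaction), 1, 11, 7 and 5 in T cells (the first 4 of these), 3, 3, 7 and 2 in NK cells, 3, 5, 41 and 11 in monocytes and macrophages, 6, 6, 14 and 2 in dendritic cells, and 52, 39, 83 and 1 in neutrophils. Where these counts were 5 or fewer the genes were, chosen after their values were seen, Slc25a37, Cep78 and Sox18 in CD45+ cells; Ndufaf1, then Slc9b2, Stx6, Tmem88, Msmo1 and Acat2 in T cells; BC051226, Gm5547 and Tpgs2, then BC051226, Zfp770 and Jmjd8, then Zfp808 and Rtp4 in NK cells. They were Isg20, Nkap and Gzmg, then Gm40194, Zbtb7b, Zfp839, Clk4 and 2610021A01Rik in monocytes and macrophages, Gda and Eogt in dendritic cells, and Igf1r in neutrophils.

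Without the filter on low counts edgeR called 23, 23, 38 and 6 genes in neutrophils in the 4 comparisons and 1 (Fn1) in dendritic cells of minP1_PDL1 against Control. With genes in at least 10% of cells it called 2, 2 and 6 in neutrophils against Control (Mtmr6 and Rasgrp4 in the first 2), 1 in CD45+ cells of minP1_PDL1 against Control (S100a9), and 1 in dendritic cells against Control (Fn1) and against PDL1 (Gda). Without the cell filter T cells of minP1_PDL1 against Control had 0 and dendritic cells of minP1_PDL1 against PDL1 had 1 (Gda), and 2 comparisons of cells and depth had an exact permutation p under 0.05. Counting cells gave 0 genes in those T cells, 1 in CD45+ cells of minP1_PDL1 against minP1 (Cx3cr1) and a reversed log2 change of 0.0306 for Rpl32 in monocytes and macrophages. Without the cluster of mixed lineage 1 gene passed in CD45+ cells of minP1_PDL1 against Control (S100a9). These genes were named after their values were seen, and the cause was not tested.

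With the replicate number as a block T cells of minP1_PDL1 against Control had 0 genes, and 94 of 101 list calls held. Against Control lists then numbered 2 each in T cells of minP1 and minP1_PDL1 and NK cells of PDL1. By edgeR the neutrophil share passed against Control in PDL1 (log2 change 1.81, with the block 1.83) and minP1_PDL1 (1.79 and 1.81). In CD45+ cells 19 same-number pairs had a median r of 0.0158 (2 over 0.1, highest 0.194). Of 14 mice 3 were closest to their own number. Number 1 had the most cells of the larger non-immune cluster in each group. That share's adjusted edgeR p was 0.508, and 0.0522 with the block. Pairing was left open.

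With an estimated correlation 0 lists passed in each of the 22 sets with any call. Without the 2 clusters of non-immune cells 8 lists passed for minP1 and 5 for PDL1 against Control in CD45+ cells, and the log2 change of Csf1 reversed to 0.29. Without the mixed cluster 3 passed for minP1_PDL1 against PDL1 in CD45+ cells, and 3, 6 and 7 in monocytes and macrophages (PDL1 and minP1_PDL1 against Control, minP1_PDL1 against PDL1). Without cells of doublet score over 0.5 no class passed in share (neutrophils, adjusted permutation p = 0.0984), 1 gene passed in dendritic cells of PDL1 against Control (Ccl4) and 1 in neutrophils of minP1_PDL1 against PDL1 (S100a8), both named after their values were seen. Lists then numbered 2 in CD45+ cells of minP1_PDL1 against PDL1. Against Control they were 2 in T cells of minP1_PDL1, and 1 and 0 in NK cells of minP1 and minP1_PDL1. They were 4 and 2 in monocytes and macrophages of minP1 and PDL1, and 2 in dendritic cells of minP1. Of single list calls 26 then ended. The median of myeloid-recruiting chemokines in dendritic cells of minP1_PDL1 against Control reversed to 0.09 (adjusted p = 0.922). The cause was not tested.

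The log2 ratio of CD8 to regulatory T cells, with T cells called by counts, reversed to 0.32 for minP1 and 0.0363 for minP1_PDL1 against Control and to -0.28 for minP1_PDL1 against minP1. None of these passed before or after.

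Leaving out each mouse in turn, 0 to 1 classes passed in share, with the adjusted permutation p of neutrophils from 0.0113 to 0.123, and their difference between minP1_PDL1 and PDL1 ran from -1.02 to 0.6675 points. Comparisons of cells and depth with an exact permutation p under 0.05 numbered 0 to 1. The CD8 to regulatory ratio ran from -0.53 to 0.0617 for minP1 and -0.33 to 0.0606 for minP1_PDL1 against Control, and from -0.17 to 0.44 for minP1_PDL1 against minP1. Genes numbered 0 to 1 in T cells of PDL1 against Control and of minP1_PDL1 against Control (Fos in the latter), and 0 to 2 in dendritic cells of minP1_PDL1 against PDL1 (Fn1 and Gda without PDL1_2). Lists in CD45+ cells numbered 1 to 6 for minP1 and 4 to 12 for PDL1 against Control and 0 to 11 for minP1_PDL1 against PDL1. In the order minP1, PDL1 and minP1_PDL1 against Control and minP1_PDL1 against PDL1 they numbered 0 to 3, 0 to 4, 1 to 3 and 0 to 3 in T cells, 0 to 3, 0 to 2, 0 to 2 and 0 to 3 in NK cells, and 0 to 5, 3 to 8, 0 to 9 and 1 to 6 in dendritic cells. In monocytes and macrophages they numbered 1 to 5, 2 to 7 and 1 to 12 in the last 3 of these, and in neutrophils 0 to 2, 0 to 6 and 0 to 2 for minP1 and PDL1 against Control and minP1_PDL1 against PDL1. Of single list calls 492 kept their side of the threshold and 173 did not. Genes of the treated axis, and those of smallest p from other comparisons, kept theirs in all 1323 cases in CD45+ cells. Under DESeq2 149 such cases kept theirs and 13 passed, none of them of the treated axis.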

Other observations

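Cell clusters outside the named types differed in their transcripts. A cluster of 144 cycling cells carried Gzmd and Gzme, granzymes of activated killer cells, with Ncr1 in 88.9%. It took 2.23%, 1.96%, 1.65% and 1.58% of cells in Control, minP1, PDL1 and minP1_PDL1. A cluster of 55 cells carried Alox15 and Ccr3, genes of eosinophils, and took 0.458%, 0.622%, 0.551% and 1.18%. A cluster of 53 cells carried Ifng and Batf, with 100% over a doublet score of 0.5 and Trac, Ncr1 and Foxp3 in 94.3%, 62.3% and 43.4%, and took 0.505%, 0.987%, 0.888% and 0.376%. A second cycling cluster of 53 cells took 0.612%, 0.518%, 0.692% and 0.950%, and a cluster of 35 cells with the osteoclast genes Ctsk and Acp5, 51.4% of them over that score, took 0.376%, 0.484%, 0.905% and 0.189%. The 42 cells of Krt19, Krt8 and Epcam, epithelial or tumour cells, took 0.477%, 0.650%, 0.417% and 0.581%.

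Tests of the 2 treatments as factors were chosen only after the group results were seen, and all 402 of them together had a smallest adjusted p of 0.164. Within the 22 lists of a cell set, with 7 mice given the antibody and 7 not, type I interferon genes in CD45+ cells differed by 0.50 (adjusted exact permutation p = 0.0314) and cholesterol genes in monocytes and macrophages by -0.59 (exact permutation p = 0.00143, adjusted p = 0.0314). In the same way DC maturation genes in NK cells were lower by 0.45 in the 8 mice given minP1 than in the 6 without it (exact permutation p = 0.000816, adjusted p = 0.0180). Immediate early genes in T cells differed by 0.38 with the antibody (adjusted exact permutation p = 0.0629).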
